A study of Mus musculus with 32 samples.

How the data were processed

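RNA sequencing had been carried out on satellite cells, the stem cells of skeletal muscle, and on fibro-adipogenic progenitors (FAPs), the interstitial mesenchymal cells of muscle, both sorted from mouse supraspinatus, a muscle of the rotator cuff. Per the labels, the muscles were injured with cardiotoxin, a snake venom toxin that destroys muscle fibres, and either received interscapular brown adipose tissue (BAT) of young donor mice or had the injury alone (control). No muscle with a sham operation or with another graft was analysed here. Per the labels, both kinds of muscle came from the same adult male C57BL/6J mice and cells were sorted at day 3 or day 7. The sort took cells without CD45 (a leukocyte marker) and without CD31 (an endothelial marker) that carried Sca1, with integrin alpha 7 present on satellite cells and absent from FAPs. Libraries were made with a low-input cDNA kit, per the labels' protocols.

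The authors deposited a table for each day with a column for each library. The deposited values are expected counts per gene, made by the authors and not normalised: the column totals differ, and 71.8% of the values above 0 equal their rounded value exactly, with no tolerance. Per the submitters' processing notes, DRAGEN and the mm10 build were used. Versions, roles, annotation, the treatment of reads that match several places and any use of strand are not given in the sources used here. Values of near-identical genes (alpha and beta globins, ribosomal proteins with their pseudogenes, class I histocompatibility genes) and of overlapping genes on opposite strands are therefore uncertain. In each table were 55774 entries, of which 287 repeated another entry with identical values and were removed, which left 55487 genes. No column lacked a sample. Of these gene identifiers 55227 are in GENCODE M21, the mm10 annotation that supplied the 1-based coordinates, and 53417 have the same symbol there.

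The 32 libraries form 8 groups of 4 (2 cell types, 2 days, BAT and control). Of each group, 3 libraries carry a replicate number in the labels, and the library without a number was named replicate 4. Mouse codes in the labels pair the BAT and the control library of a mouse, with 4 mice per day, 8 in all. At day 3 the labels of satellite cell replicate 3 and FAP replicate 4, BAT and control, hold no such code. These 4 libraries were taken to come from the same mouse, which is an inference. At day 3 the same replicate number marks different mice in the 2 cell types, and comparisons across cell types used the mouse, not the number. Because the labels say that paired samples came from the same mouse, the mouse was a block in every comparison within a day. For differences of BAT effects between cell types the block was the mouse within a cell type (8 blocks). There the 2 cell types of a mouse were not linked. The deviations of paired libraries from their group means had a mean correlation over genes of -0.0326 (range -0.357 to 0.323) for satellite cells at day 3, 0.365 (0.147 to 0.514) at day 7, 0.145 (-0.0618 to 0.327) for FAPs at day 3 and 0.519 (0.400 to 0.689) at day 7. Own partners were the best match for 0, 4, 3 and 4 of the 4 mice. No 2 libraries of a group were alike within counting noise (smallest chi-square per degree of freedom 17.3).

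Expected counts were rounded to whole numbers, which moved no library total by more than 0.00034%. Genes were tested with edgeR's quasi-likelihood F test after TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each comparison used only the libraries of its groups. The comparisons were BAT against control in each cell type and day, the difference of the BAT effect between days and between cell types, satellite cells against FAPs in control muscle on each day, and day 7 against day 3 in control muscle of each cell type. Day 3 and day 7 libraries come from different mice and different deposited tables, so day cannot be told apart from table or any batch that goes with it. Log2 changes are given with standard errors (SE) taken as the absolute change over the square root of F. Levels are CPM (gene counts over the library total, scaled to a common total) adjusted by TMM within a comparison as mean ± SD (n = 4), and levels of check genes and of single libraries are plain CPM.

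Lists of 29 gene groups were fixed before the data were examined: satellite cell identity, myogenic differentiation, mature myofibre, FAP identity, extracellular matrix, brown and beige adipocyte, adipogenesis, macrophage and monocyte, neutrophil, lymphocyte, endothelial, pericyte and smooth muscle, Schwann and glial, tenocyte, erythroid, cell cycle, inflammatory cytokines and NF-kB targets, interferon response, nuclear oxidative phosphorylation, mitochondrially encoded, fatty acid oxidation, glycolysis, hypoxia, immediate-early, unfolded protein response, oxidative stress defence, p53 targets, secreted growth factors and ribosomal proteins. Lists with at least 3 tested members were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the members of a list move one way on balance without comparing them with other genes, are given beside it. The 1 erythroid member Ahsp was not found in the tables.

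The rule for named genes was also fixed before the data were examined. For BAT against control it took up to 8 higher and 8 lower called genes with the largest change, a mean log2 CPM of at least 2 and the same sign in 4 of 4 mice, or the 3 with the smallest p, named as not passing, where a direction had none. It took further up to 3 called members of each list, or the 2 with the smallest p of a called list with no called member. For differences of BAT effects it took up to 4 genes per direction, and for cell types and days up to 5 per direction and 2 per list. Pax7, Myod1, Itga7, Ly6a, Pdgfra, Ptprc, Pecam1, Ucp1 and Adipoq were always read as checks. Some genes that the rule takes are not reported here.

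Library measures (total count, genes detected, share of the 20 most abundant genes, shares of mitochondrially encoded and ribosomal protein genes) were compared between BAT and control with exact two-sided sign-flip permutation tests over 4 pairs, whose smallest possible p is 0.13. Alternatives chosen before the data were examined were other size factors, no filter, DESeq2, limma voom with sample weights, no block, a joint fit of all 32 libraries, and leaving out each replicate. Fits without the mice that held macrophage-rich libraries, list tests for the differences of BAT effects, and leaving out each replicate in the list tests with an estimated correlation were added after the data had been seen.

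The procedure was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For BAT against control, edgeR recovered 38% and 77% of these in satellite cells at day 3, 78% and 96% at day 7, 58% and 90% in FAPs at day 3, and 65% and 90% at day 7. Among the genes it called in these 4 simulations the false share was 5.74%, 6.63%, 7.65% and 6.59%, and with DESeq2 it was 16.1%, 11.1%, 14.1% and 10.6%. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.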

Results

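Transcriptomes of satellite cells and fibro-adipogenic progenitors (FAPs) were measured to ask how a transplant of brown adipose tissue (BAT) alters the response of the supraspinatus muscle to cardiotoxin injury. There were 32 libraries in 8 groups of 4: each cell type at day 3 and day 7 after injury, from muscle with BAT and from control muscle of the same mouse, with 4 mice per day. Total counts ranged from 19.8 M to 46.4 M per library (median 25.7 M). A count of 0 allows a level of up to 0.065 CPM in the deepest and 0.15 CPM in the shallowest library (3 counts of the total). These limits cover counting error only. With 4 pairs none of 20 tests of library measures could pass (exact sign-flip permutation tests, smallest possible p = 0.13), so that differences are given as values. In FAPs total counts were higher with BAT in 4 of 4 mice at day 3 (difference 3.00 ± 2.91 M, SD) and in 0 of 4 at day 7 (-2.15 ± 2.57 M). The share of mitochondrially encoded transcripts in satellite cells at day 7 was 3.75% in control and 4.40% with BAT. The difference within a mouse was 0.644 ± 0.304 percentage points (SD, n = 4), above 0 in 4 of 4 mice.

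The markers of the sort separated the cell types. Pax7, the transcription factor of satellite cells, was at 30.3 ± 7.22 CPM (SD, n = 4) in control satellite cells at day 3 and at 122 ± 44.6 CPM at day 7, against 0 and 0.136 ± 0.272 CPM in control FAPs. Pdgfra, the receptor that marks FAPs, was at 324 ± 79.7 and 294 ± 33.8 CPM in control FAPs and at 3.92 ± 6.66 and 2.95 ± 2.73 CPM in control satellite cells. Itga7, the integrin used in the sort, was at 428 ± 123 CPM in control satellite cells at day 3 and at 4.04 ± 1.20 CPM in FAPs. Ly6a, which encodes Sca1, was at 826 ± 125 CPM in control FAPs at day 3 but at 11.1 ± 14.4 CPM in control satellite cells. The labels describe both gates as Sca1 positive. Pecam1 (CD31) was at most 12.5 CPM in any library. Ucp1, the uncoupling protein of brown fat, was at most 0.436 CPM in every library except that of FAP control replicate 4 at day 7 (13.0 CPM), and Adipoq, an adipokine of fat cells, was at most 3.15 CPM.

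3 day 3 libraries were rich in macrophage transcripts. The summed level of 26 macrophage and monocyte genes was 4716 CPM in satellite cell control replicate 3, 4785 CPM in satellite cell BAT replicate 4 and 10479 CPM in FAP BAT replicate 1. It was 916 to 1376 CPM in the other 6 satellite cell and 261 to 1036 CPM in the other 7 FAP libraries of that day. In these 3 libraries Lyz2, the lysozyme of myeloid cells, reached 953, 1058 and 2530 CPM. Ptprc, which encodes CD45, reached 9.91, 10.3 and 34.0 CPM, although the sort excluded CD45-positive cells. In the day 7 mouse of replicate 3, the female-specific transcript Xist was at 163 to 355 CPM in all 4 libraries and the Y-linked Ddx3y at 0. Xist was at most 0.161 CPM and Ddx3y at least 29.1 CPM in the 28 libraries of the other mice. The labels describe the mice as male.

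**Figure D1:**
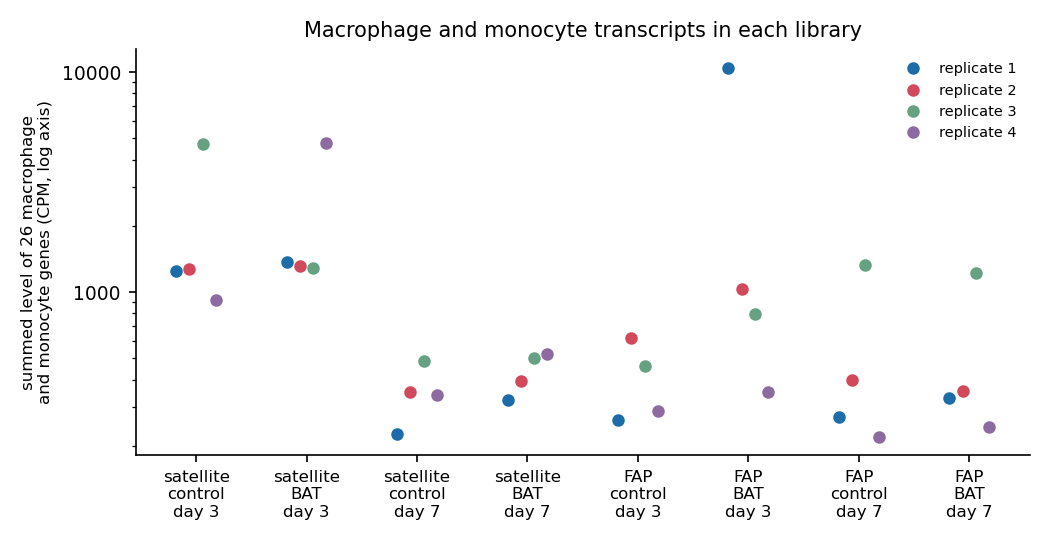
Summed level of 26 macrophage and monocyte genes (CPM, log axis) in each of the 32 libraries by group, a point per library coloured by replicate. At day 3, satellite cell control replicate 3 (4716 CPM), satellite cell BAT replicate 4 (4785 CPM) and FAP BAT replicate 1 (10479 CPM) stand above the other libraries of their groups.

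In control muscle the 2 gates held distinct programmes on both days. At day 3 the muscle regulator Myog was at 0.0936 ± 0.0785 to 649 ± 314 CPM from FAPs to satellite cells (log2 difference 12.71 ± 0.27 SE, edgeR adjusted p = 1.03e-06), and Chrng, a fetal subunit of the acetylcholine receptor, at 0.0105 ± 0.0210 to 83.7 ± 20.6 CPM. Chrnd, another subunit of that receptor, had 0 counts in the 4 control FAP libraries and 128 ± 27.8 CPM in satellite cells, at least 4387-fold higher (floor of 3 counts over the group), and Pax7 was at least 1040-fold higher. FAPs held the matrix protein gene Mfap5 (1517 ± 324 to 10.8 ± 15.6 CPM from FAPs to satellite cells), complement C3 (356 ± 54.0 to 3.03 ± 5.30 CPM) and Aldh1a2, an enzyme of retinoic acid synthesis (153 ± 46.4 to 0.889 ± 1.78 CPM). At day 7, C3 (log2 difference -9.07 ± 0.22), Clec3b (-8.28 ± 0.29) and the growth factor gene Gdf10 (-8.10 ± 0.40) were again higher in FAPs. Calcr, the calcitonin receptor of quiescent satellite cells (10.06 ± 0.55), was higher in satellite cells, and Pax3 was at least 691-fold higher there. Over all genes tested, edgeR called 5841 higher and 5861 lower in satellite cells of 16329 at day 3, and 3812 higher and 3839 lower of 16969 at day 7.

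The fixed lists showed the same separation by counts of called members. Of the myogenic list, 29 members were higher and 1 lower in satellite cells of 31 tested at day 3 (adjusted over the list alone, 29 and 1), and 30 of 32 were higher at day 7 (32 over the list alone). Of the FAP identity list all 24 tested members were lower in satellite cells at day 3 and all 24 at day 7, the same counts as over the list alone. The extracellular matrix list had 38 of 38 and 35 of 38 members lower (over the list alone 38 and 36), and the inflammatory list 23 of 26 and 25 of 25 (23 and 25). Cell cycle genes were higher in satellite cells, 38 and 39 of 40, as were nuclear oxidative phosphorylation genes, 49 and 44 of 50, and mature myofibre genes, 8 of 9 and 16 of 16. Over the list alone the counts were 38 and 39, 49 and 46, and 8 and 16. The satellite cell identity list had 17 of 21 and 18 of 22 members higher (17 and 18 over the list alone), among them Asb5 (8.77 ± 0.12 at day 3) and the chemokine receptor Cxcr4 (5.50 ± 0.27 at day 7). Its summed level at day 3 was lower in control satellite cells (3549 ± 370 CPM, SD) than in control FAPs (6864 ± 705 CPM), although most members were higher. At day 7 the sum was higher in satellite cells (9121 ± 1042 against 4658 ± 1209 CPM). Markers of other cell types also parted the gates: 9 of 11 Schwann and glial genes were higher in satellite cells at day 3, and 8 of 10 tenocyte genes were lower at day 7 (9 and 8 over the list alone). Camera called 17 of 27 lists at day 3 and 19 of 28 at day 7, and fry 21 and 22. With an estimated correlation camera called 0 on either day, and the lowest adjusted p with an estimated correlation was 0.214 at day 3 and 0.0883 at day 7.

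The first question for the transplant was whether it altered satellite cells at day 3. No gene passed. edgeR called 0 of 15631 genes, with 472 at an unadjusted p under 0.05, where chance gives about 782. DESeq2 and limma voom also called 0. Among the genes with the smallest p, none of which passed, were Tubg1, a gamma tubulin of the centrosome (69.3 ± 14.1 to 86.1 ± 11.8 CPM from control to BAT, log2 change 0.33 ± 0.07 SE, adjusted p = 1.000), Def8 (0.32 ± 0.08), Dph1 (0.29 ± 0.07), Id1, an inhibitor of differentiation factors (798 ± 35.7 to 637 ± 65.6 CPM, -0.33 ± 0.08), Tent5b (-0.56 ± 0.12) and Lrrn1 (-0.29 ± 0.07). In simulated data of this comparison edgeR recovered 77% of genes changed 4-fold and 38% of those changed 2-fold, the latter the lowest share of the 4 BAT comparisons.

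At the level of gene lists, satellite cells of day 3 showed shifts that rested on the preset correlation. The extracellular matrix list rose (37 of 38 members fitted above 0, median log2 change 0.50, camera adjusted p = 9.10e-10), but its median was above 0 in only 2 of 4 mice (mean 0.45 ± 1.60 SD), with the collagen chaperone Serpinh1 at 0.31 ± 0.12 and the protease inhibitor Timp1 at 0.30 ± 0.13, neither past the test. The inflammatory list rose (20 of 22, median 1.21, adjusted p = 6.90e-09, above 0 in 3 of 4 mice), with Saa3 at 3.16 ± 1.19 and Il6 at 1.86 ± 1.01, neither past the test. The lists of glycolysis (adjusted p = 1.31e-04), interferon response (2.16e-04), FAP identity (0.00140), erythroid (0.00999), tenocyte (0.0259) and unfolded protein response genes (0.0259) rose. Those of mitochondrially encoded (0.00140) and nuclear oxidative phosphorylation genes (0.0259) fell. The list median was above 0 in 2 of 4 mice for FAP identity, tenocyte, mitochondrially encoded and nuclear oxidative phosphorylation genes and in 3 of 4 for glycolysis, interferon, erythroid and unfolded protein response genes. The mean was 0.50 ± 2.61 (SD) for FAP identity and 1.27 ± 2.44 for tenocyte genes. All 10 calls were lost with an estimated correlation (adjusted p = 0.815 for 9 lists and 0.841 for nuclear oxidative phosphorylation, with an estimated correlation). With fry they were lost too (adjusted p = 0.923 each), and adjusted over the list alone 0 members passed in any of the 10. The macrophage list, rich in 2 of these 8 libraries, had 21 of 22 members fitted above 0 but did not pass (adjusted p = 0.154), and neither did the neutrophil list (adjusted p = 0.225). Without the 2 pairs that held a macrophage-rich library, 1 gene passed, the beta globin Hbb-bt (adjusted p = 0.0424). Of the 2 pairs left, that of replicate 2 had an erythroid sum of 712 CPM with BAT and 10.4 CPM in control, against 15.9 to 154 CPM in the other 3 BAT libraries. Without those pairs 6 of the 10 lists passed in the same direction, and without replicate 4, whose BAT library was macrophage-rich, 0 did. All 10 did without replicate 3, whose control library was macrophage-rich, and 8 did without replicate 1. Without replicate 2, whose BAT library had the highest tenocyte sum of its group (643 CPM), 4 did, and the erythroid list had an adjusted p of 0.665. The direction turned without replicate 2 for the tenocyte and nuclear oxidative phosphorylation lists (adjusted p = 0.452 and 0.356) and without replicate 4 for the FAP identity and interferon lists (0.442 and 0.638). Leaving out replicates 2, 3 and 4 in turn gave 6, 16 and 5 called lists. Over all genes the BAT libraries of replicates 3 and 4 correlated better with the control of each other's mouse (r = 0.416 and 0.525 of deviations from the group mean) than with their own (-0.357 and -0.222). Over 242 genes higher in satellite cells they correlated better with their own (0.923 and 0.819 against -0.314 and -0.416).

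At day 7, transcripts of mature muscle fibres were lower in satellite cells from muscle with BAT than in those from control muscle of the same mouse. 3 genes fell. Myh4, the myosin heavy chain of fast type IIb fibres, went from 38.9 ± 25.4 to 14.8 ± 9.38 CPM (SD, n = 4 each; log2 change -1.39 ± 0.12 SE, edgeR adjusted p = 0.00595). Mybpc2, the fast skeletal myosin binding protein C, went from 44.6 ± 23.7 to 21 ± 12.1 CPM (-1.13 ± 0.12, adjusted p = 0.0125). Ckm, the muscle creatine kinase, went from 644 ± 388 to 322 ± 221 CPM (-1.05 ± 0.11, adjusted p = 0.0115). Each was lower with BAT in 4 of 4 mice. In mm10 (1-based, GENCODE M21 gene bounds) they are Myh4 (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446, plus strand), Mybpc2 (ENSMUSG00000038670, chromosome 7, 44501699 to 44524656, minus strand) and Ckm (ENSMUSG00000030399, chromosome 7, 19404776 to 19422841, plus strand).

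**Figure D2:**
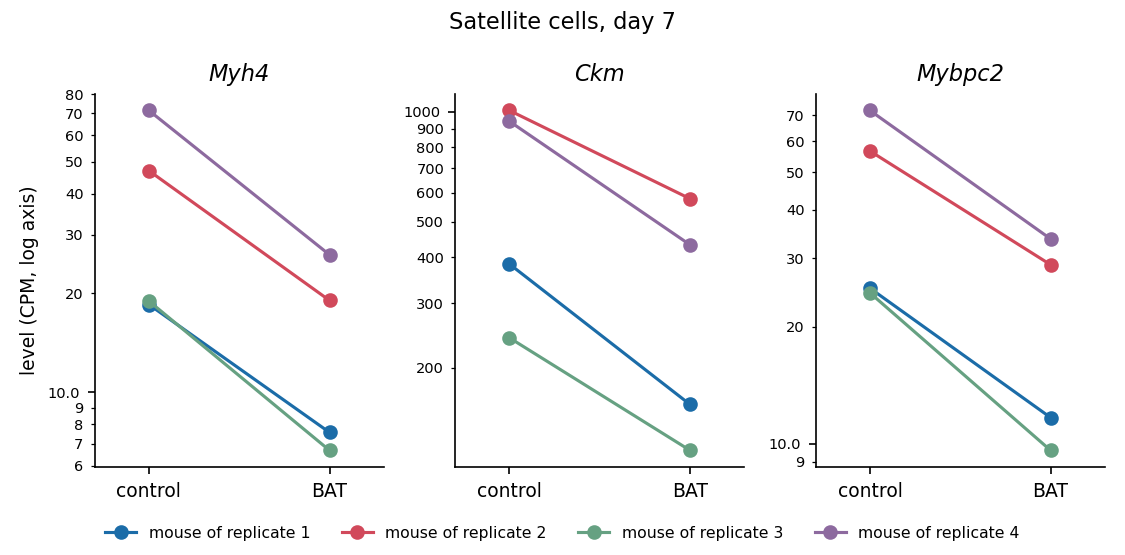
Levels (CPM, log axis) of Myh4, Ckm and Mybpc2 in satellite cells at day 7, with a line per mouse from its control to its BAT library. Each gene is lower with BAT in 4 of 4 mice.

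The mature myofibre list as a whole fell: all 16 tested members were fitted below 0, with a median log2 change of -0.56 (camera adjusted p = 9.26e-33, adjusted p = 0.0395 with an estimated correlation, fry adjusted p = 0.0271). Its median was below 0 in 4 of 4 mice (mean -0.61 ± 0.13 SD). Over all genes tested 2 of its 16 members were called lower, and adjusted over the list alone 12 were: Myh4, Mybpc2, the Z-disc genes Myoz1, Tcap and Actn3, the calcium handling genes Pvalb, Atp2a1 and Casq1, the glycolytic Pgam2 and Eno3, Myh1 and myoglobin (Mb). The myogenic list fell as well (29 of 32 fitted below 0, median -0.23, adjusted p = 2.65e-16, adjusted p = 0.280 with an estimated correlation, so that this call was lost). Of its members 1 was called over all genes and 8 over the list alone, Ckm with the actins Acta1 and Actc1 and the sarcomere genes Tnnt3, Myl1, Mylpf, Tnni2 and Tnnc2. The satellite cell identity list fell (p = 0.0303, adjusted p = 0.647 with an estimated correlation), with Itga7 at -0.41 ± 0.13 and the signalling inhibitor Spry1 at -0.31 ± 0.10, neither past the test. The median was above 0 in 0 of 4 mice for the myogenic and in 1 of 4 for the satellite cell identity list.

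Other lists moved in satellite cells at day 7 under the preset correlation alone. All 13 mitochondrially encoded genes were fitted above 0 (median 0.27, adjusted p = 2.04e-11, adjusted p = 0.573 with an estimated correlation), with mt-Nd2 at 0.43 ± 0.11 and mt-Co1 at 0.37 ± 0.11. Adjusted over the list alone 9 of them were higher and over all genes 0. The lists of ribosomal proteins (8.66e-05), cell cycle (0.00283), oxidative stress defence (0.00610), unfolded protein response (0.00610) and inflammatory genes (0.00583) rose. That of extracellular matrix genes fell (1.97e-04). All 6 of these calls were lost (adjusted p from 0.573 to 0.647 with an estimated correlation). The list median was above 0 in 4 of 4 mice for oxidative stress and unfolded protein response genes and in 3 of 4 for ribosomal proteins. It was above 0 in only 2 of 4 for cell cycle (mean 0.10 ± 0.15 SD), inflammatory (0.25 ± 0.56) and extracellular matrix genes (-0.15 ± 0.30). Within them Cilp, a matrix protein of cartilage and tendon, was at 243 ± 153 to 126 ± 69.4 CPM (-0.89 ± 0.11, adjusted p = 0.0524), Ccnb1 at 0.34 ± 0.10, Gclc at 0.40 ± 0.17 and the chemokine gene Ccl11 at 0.98 ± 0.26, none past the test. Among markers of other cell types the tenocyte (p = 1.66e-05) and Schwann lists (0.00610) fell and the pericyte (1.72e-05) and macrophage lists (0.0105) rose, all lost (adjusted p = 0.573, 0.574, 0.647 and 0.647 with an estimated correlation). Their medians were above 0 in 1, 1, 3 and 3 of 4 mice. Over the list alone 3 tenocyte and 2 Schwann genes were lower, and 2 pericyte and 2 macrophage genes higher. Thbs4 was at -0.70 ± 0.12, the myelin gene Mbp at -0.46 ± 0.13, the pericyte gene Rgs5 at 0.69 ± 0.20 and Spp1 at 0.41 ± 0.11, none past the test. The fatty acid binding protein Fabp4 (19.4 ± 11.9 to 42.1 ± 18.3 CPM, 1.24 ± 0.23, adjusted p = 0.238) and haptoglobin, Hp (1.34 ± 0.27), had the smallest p of the genes fitted higher and did not pass. The brown and beige adipocyte list did not pass (adjusted p = 0.953), nor did the lymphocyte list (adjusted p = 0.431).

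In all, edgeR called 0 higher and 3 lower of 16868 genes in satellite cells at day 7, with 1261 at an unadjusted p under 0.05, where chance gives about 843. The counts were 4 higher and 35 lower with DESeq2 and 5 lower with limma voom, both holding all 3 genes. Without the mouse as a block and in the joint fit of all 32 libraries 0 genes passed, and without the filter on low counts 206 did. Leaving out replicates 1, 2, 3 and 4 in turn left 1, 14, 1 and 0. Myh4 passed without replicates 1, 2 and 3 (adjusted p = 0.0456, 0.0121 and 0.0331), Ckm and Mybpc2 without replicate 2 alone, and each of the 3 had an adjusted p of 0.239 without replicate 4. Of the 14 called lists, 11, 10, 10 and 11 passed in the same direction. The mature myofibre list passed with the preset correlation in each of these 4 fits, but with an estimated correlation its adjusted p was 0.392, 0.310, 0.268 and 0.137.

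In FAPs at day 3, inflammatory genes were higher in muscle with BAT. 3 genes rose. Saa3, an acute-phase serum amyloid protein, went from 15.1 ± 11.2 to 73.3 ± 39.8 CPM (SD, n = 4 each; log2 change 2.36 ± 0.15 SE, edgeR adjusted p = 0.00581). Cxcl5, a chemokine that attracts neutrophils, went from 532 ± 224 to 1199.8 ± 529 CPM (1.17 ± 0.08, adjusted p = 0.00591). Ereg, the growth factor epiregulin that binds the EGF receptor, went from 17.8 ± 9.80 to 52.6 ± 17.2 CPM (1.67 ± 0.14, adjusted p = 0.0204). Each was higher with BAT in 4 of 4 mice. In mm10 they are Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, plus strand) and Ereg (ENSMUSG00000029377, chromosome 5, 91074622 to 91093646, plus strand).

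**Figure D3:**
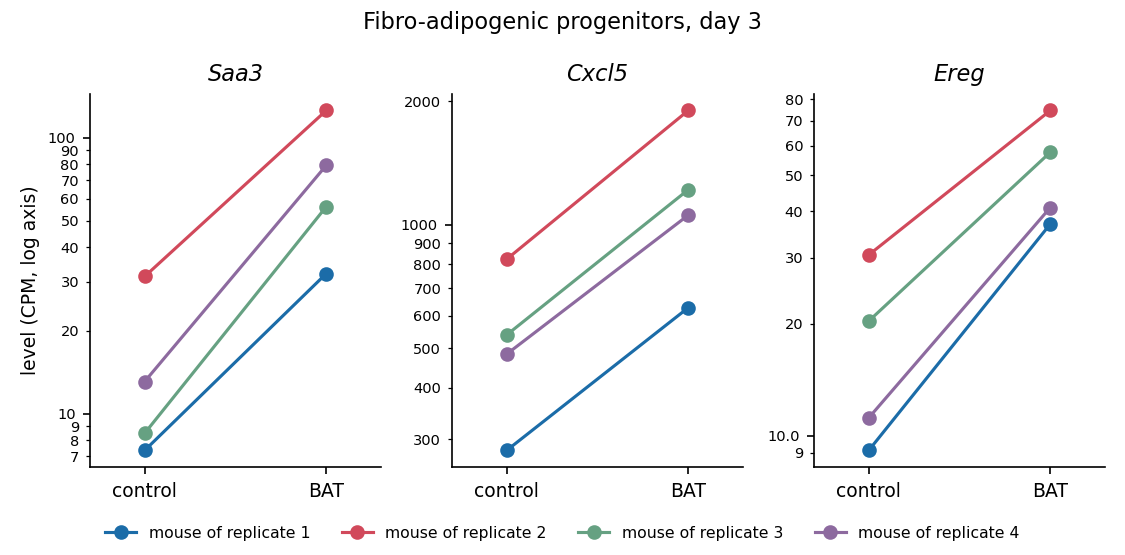
Levels (CPM, log axis) of Saa3, Cxcl5 and Ereg in FAPs at day 3, with a line per mouse from its control to its BAT library. Each gene is higher with BAT in 4 of 4 mice, including replicate 1, whose BAT library was rich in macrophage transcripts.

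The list of inflammatory cytokines and NF-kB targets rose in FAPs at day 3: 20 of 25 tested members were fitted above 0, with a median log2 change of 0.41 (camera adjusted p = 1.22e-39, adjusted p = 0.0367 with an estimated correlation, fry adjusted p = 0.0479). Its median was above 0 in 4 of 4 mice (mean 0.48 ± 0.27 SD). Over all genes 2 members were called higher, and adjusted over the list alone 12 were: Saa3, Cxcl5, the cytokines Lif, Il6, Il33 and Csf2, the chemokines Cxcl1 and Cxcl2, the iron binding lipocalin Lcn2, the enzymes Ptgs2 (prostaglandin synthesis) and Nos2 (nitric oxide synthesis), and the Il33 receptor Il1rl1. The oxidative stress list rose (p = 4.75e-07, adjusted p = 0.141 with an estimated correlation), with the superoxide dismutase Sod2 at 77.1 ± 25.4 to 133 ± 22.1 CPM (0.82 ± 0.10, adjusted p = 0.152) and the haem oxygenase Hmox1 at 0.49 ± 0.12. Neither gene passed over all genes, and 2 members of the list did over the list alone.

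Metabolic and stress lists also moved in FAPs at day 3, with calls that were lost with an estimated correlation. The glycolysis list rose (16 of 16 fitted above 0, p = 1.49e-10, adjusted p = 0.473 with an estimated correlation), with the glucose transporter Slc2a1 at 0.71 ± 0.16 and Eno1 at 0.38 ± 0.13. The hypoxia list rose (p = 2.52e-06, adjusted p = 0.476 with an estimated correlation), with Ndrg1 at 0.37 ± 0.10 and Pfkfb3 at 0.50 ± 0.17. The FAP identity list fell (21 of 24 fitted below 0, p = 3.15e-07, adjusted p = 0.303 with an estimated correlation), with Mfap5 at -0.30 ± 0.09 and Cd55 at -0.44 ± 0.13. The lists of the unfolded protein response (p = 1.69e-04), p53 targets (0.00606), adipogenesis (0.0264) and fatty acid oxidation (0.0410) rose, all lost (adjusted p from 0.463 to 0.745 with an estimated correlation), with Fabp4 at 1.05 ± 0.28 and the pyruvate dehydrogenase kinase Pdk4 at 0.63 ± 0.19. Without replicate 1 the lists of p53 targets, adipogenesis and fatty acid oxidation did not pass (adjusted p = 0.228, 0.0668 and 0.978), and the last had a median above 0 in 2 of 4 mice. The median was above 0 in 4 of 4 mice for the other 5 of these lists that rose and in 0 of 4 for FAP identity. None of the genes named for these lists passed, and over the list alone 1 glycolysis gene and 0 of the others did. Of the genes fitted lower with the smallest p, the connective tissue growth factor Ccn2 was at 457 ± 60.8 to 306 ± 50.2 CPM (-0.58 ± 0.10, adjusted p = 0.462) and did not pass.

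Markers of other cell types moved with BAT in these FAP libraries, which include the macrophage-rich BAT library of replicate 1. The macrophage list rose (p = 4.76e-12, adjusted p = 0.489 with an estimated correlation), with all 22 members fitted above 0, and its summed level was 407 ± 166 CPM in control and 3165 ± 4884 CPM with BAT. The myogenic (p = 0.00117), mature myofibre (0.0374) and erythroid lists (0.00159) rose too, and each call was lost (adjusted p = 0.630, 0.602 and 0.489 with an estimated correlation). Their sums were high in the BAT library of replicate 1 alone: 627 CPM for myogenic genes against 323 to 359 CPM in the other 3 BAT libraries, 125 against 9.62 to 14.0 CPM for mature myofibre genes and 409 against 2.60 to 32.5 CPM for erythroid genes. Without replicate 1 none of these 3 lists passed (adjusted p = 0.978 for myogenic, with the direction turned, 0.952 for mature myofibre and 0.285 for erythroid), while the macrophage list did (0.00186). The macrophage median was above 0 in 2 of 4 mice, but the summed level was higher with BAT in each mouse. Beside replicate 1, it went from 618 CPM in control to 1036 CPM with BAT in replicate 2. In replicate 3 it went from 462 to 796 CPM and in replicate 4 from 287 to 350 CPM. The endothelial (adjusted p = 0.229) and tenocyte lists (0.516) did not pass. Over the 3 pairs without that library the median of the inflammatory list was still above 0 in each mouse (mean 0.35 ± 0.0859 SD).

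In all, edgeR called 3 higher and 0 lower of 15948 genes in FAPs at day 3, with 730 at an unadjusted p under 0.05, where chance gives about 797. The counts were 37 higher and 3 lower with DESeq2 and 10 with limma voom, both holding all 3 genes. Without the mouse as a block 0 genes passed, in the joint fit of all 32 libraries 9 others did, and without the filter 63 did. Leaving out replicates 1, 2, 3 and 4 in turn left 27, 2, 0 and 0. All 3 genes passed without replicate 1, and Saa3 also without replicate 2 (adjusted p = 0.0442). Without replicates 3 and 4 the adjusted p was 0.117 and 0.177 for Saa3, 0.197 and 0.177 for Cxcl5, and 0.44 and 0.457 for Ereg. The inflammatory list passed with the preset correlation in each of these 4 fits, but with an estimated correlation its adjusted p was 0.184, 0.193, 0.184 and 0.164.

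In FAPs at day 7 no gene passed with edgeR. It called 0 of 16021 genes, with 783 at an unadjusted p under 0.05, where chance gives about 801. The counts were 15 higher and 11 lower with DESeq2, 1 with limma voom and 145 without the filter on low counts. The genes with the smallest p were Arc, an immediate-early gene (93.3 ± 17.1 to 157 ± 48.9 CPM from control to BAT, log2 change 0.71 ± 0.12, adjusted p = 0.953), Phldb2 (0.50 ± 0.09), Rgs16 (0.68 ± 0.12), the myocilin gene Myoc (-0.84 ± 0.15), Hmcn2 (-0.50 ± 0.09) and Coch (-1.27 ± 0.25), none past the test. Without replicate 2 it called 1 gene.

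Gene lists moved in FAPs at day 7 under the preset correlation. The erythroid list fell, with all 5 members fitted below 0 (median -1.87, p = 9.74e-16, adjusted p = 0.269 with an estimated correlation) and the beta globin Hbb-bs at 21.3 ± 9.44 to 5.65 ± 4.36 CPM (-2.04 ± 0.41). All 5 passed when adjusted over the list alone and 0 over all genes. The cell cycle list rose (37 of 40 fitted above 0, median 0.24, p = 9.71e-13, adjusted p = 0.398 with an estimated correlation), with the topoisomerase Top2a at 0.37 ± 0.10 and the spindle gene Tpx2 at 0.50 ± 0.16. The tenocyte list fell (p = 1.07e-09, adjusted p = 0.398 with an estimated correlation), with Kera at -0.61 ± 0.13 and Tnmd at -0.57 ± 0.14, and 3 members passed over the list alone. The immediate-early (adjusted p = 3.23e-05), inflammatory (1.63e-04) and unfolded protein response lists (4.09e-04) rose. The FAP identity (1.33e-04), ribosomal protein (0.00356), mature myofibre (0.00582) and nuclear oxidative phosphorylation lists (0.0304) fell. These 7 calls were lost (adjusted p from 0.269 to 0.833 with an estimated correlation). The median was above 0 in 4 of 4 mice for the cell cycle list and these 3 that rose, in 2 for ribosomal proteins, in 0 for erythroid genes and in 1 for the other 4 that fell. Without replicate 1 the ribosomal protein list turned (adjusted p = 0.977). Fosb was at 0.42 ± 0.11, Csf1 at 0.41 ± 0.11, Ly6c1 at -0.48 ± 0.13 and Mybpc2 at -1.03 ± 0.36, none past the test. Leaving out replicates 1, 2, 3 and 4 in turn, 7, 10, 7 and 9 of the 10 called lists passed in the same direction. Leaving out replicate 2 moved the number of called lists from 10 to 17.

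**Figure D4:**
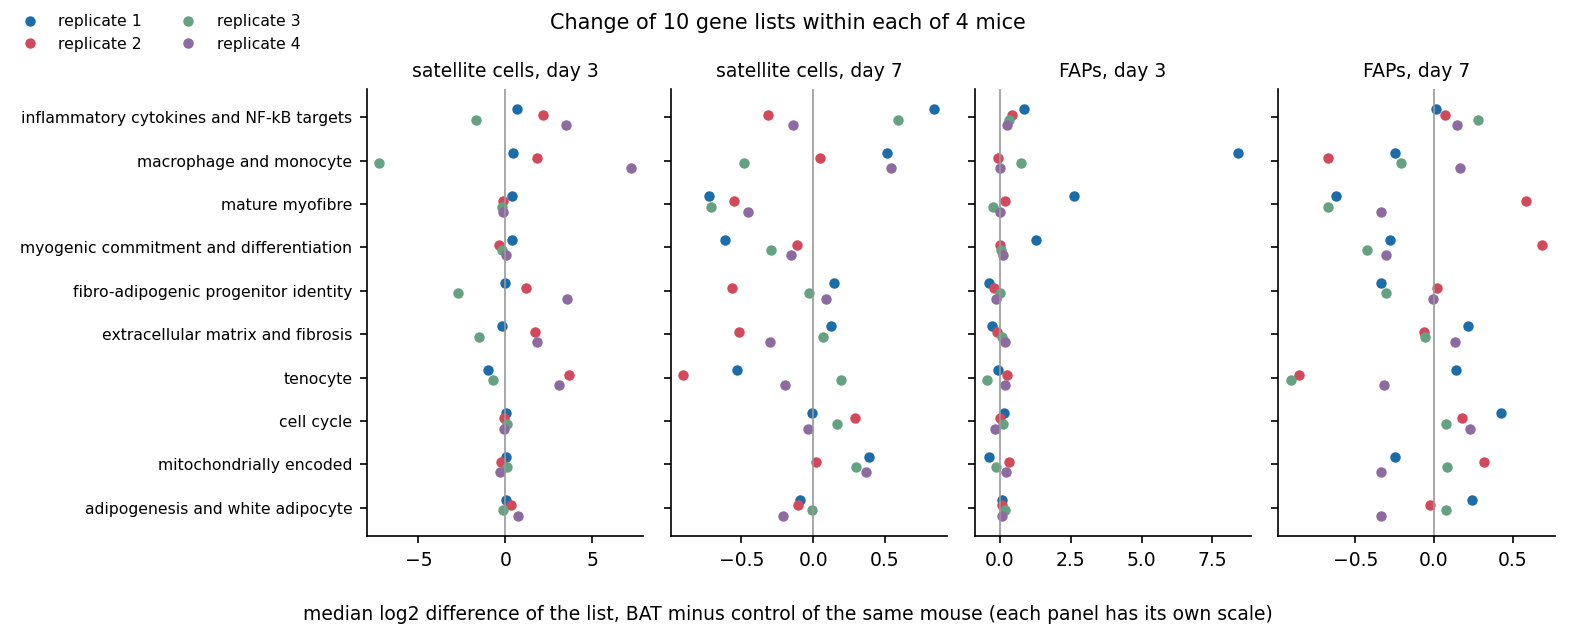
Median log2 difference between the BAT and the control library of a mouse for 10 gene lists, with a panel per cell type and day (each with its own scale) and a point per mouse. The mature myofibre list is below 0 in 4 of 4 mice in satellite cells at day 7 and the inflammatory list above 0 in 4 of 4 mice in FAPs at day 3.

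Whether the BAT effect differed between days or between cell types was tested directly. Between days edgeR called 0 of 17774 genes in satellite cells (910 at an unadjusted p under 0.05, DESeq2 8, limma voom 0) and 0 of 17284 in FAPs (579, DESeq2 1, limma voom 0). Chance gives about 889 and 864 genes at such a p. In satellite cells Ckm had a log2 difference of the effects, day 7 minus day 3, of -1.43 ± 0.21 (adjusted p = 0.372) and the adenylate kinase Ak1 of -0.84 ± 0.11 (0.372). In FAPs the difference was -2.16 ± 0.40 for Saa3 and -0.69 ± 0.16 for Lif (adjusted p = 1.000 each), none past the test. Of the lists, tested for these differences only after the data had been seen, camera called 14 of 29 in satellite cells and 15 of 28 in FAPs, and 0 with an estimated correlation. The mature myofibre list fell in satellite cells (1.55e-07, adjusted p = 0.168 with an estimated correlation) and the inflammatory list in FAPs (3.41e-08, adjusted p = 0.0607 with an estimated correlation). Leaving out the day 7 mouse of replicate 3 gave 1 gene in FAPs.

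Between cell types edgeR called 0 higher and 4 lower of 17445 genes at day 3 (550 at an unadjusted p under 0.05, DESeq2 12, limma voom 0) and 0 of 18033 at day 7 (1205, DESeq2 10, limma voom 0). Chance gives about 872 and 902 genes at such a p. The 4 called at day 3 were Chrnd (satellite cells minus FAPs, adjusted p = 0.00495), the lipoxygenase Alox5, the lectin gene Mgl2 and the nucleoporin Nup210 (0.0383 for each of these 3). All were present in every satellite cell library of the day, Chrnd at 104 to 167 CPM and Alox5 at 8.32 to 16.6 CPM. Mgl2 was at 19.3 to 25.1 CPM there and Nup210 at 19.1 to 34.8 CPM. Chrnd, Mgl2 and Nup210 had 0 counts in the 4 control FAP libraries of the day and Alox5 had 1, so that fitted log2 differences depend on the prior count and are no measure of size. They rested on the BAT library of FAP replicate 1: Chrnd had 281 counts (10.2 CPM) there and 0 in the other 7 FAP libraries of the day. Satellite cell markers were also higher in that library, with Myod1 at 34.0, Itga7 at 37.3 and Pax7 at 1.20 CPM. The other 7 held at most 0.341, 5.58 and 0 CPM. The source of these transcripts was not tested. Without the mouse of that library, or without the mouse of FAP replicate 3, 0 genes passed. Without that of FAP replicate 2 there were 4, 1 of them among these 4, and without that of FAP replicate 4 there were 12, 3 of them among these. Camera called 16 of 29 lists at day 3 and 12 of 28 at day 7, and 0 with an estimated correlation (lowest adjusted p = 0.725 and 0.408). At day 7 Ak1 (-0.81 ± 0.14) and the chemokine gene Ccl8 (2.48 ± 0.51) were among the genes with the smallest p (adjusted p = 0.691). Across genes, which are not independent replicates, 4 relations between BAT effects were computed, and those of day 3 and day 7 had a Pearson r of 0.0437 (Spearman -0.00151) in satellite cells and 0.0935 (0.155) in FAPs. Those of satellite cells and FAPs, sorted from the same muscles, had a Pearson r of 0.293 (0.216) at day 3 and 0.0319 (-0.00904) at day 7. Without the mouse as a block the Pearson r was 0.138 between cell types at day 3 and -0.0388 between days in satellite cells. The macrophage-rich BAT libraries of satellite cell replicate 4 and FAP replicate 1 came from the same muscle, which enters both effects of day 3.

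Between day 3 and day 7, most cell cycle genes fell in control satellite cells, and most genes of the mature myofibre and interferon lists rose. Parvalbumin (Pvalb), a calcium buffer of fast fibres, rose from 0.332 ± 0.0639 to 117 ± 46.2 CPM (log2 change 8.41 ± 0.38 SE, edgeR adjusted p = 8.24e-07), Myoz1 from 0.381 ± 0.0469 to 82.4 ± 32.4 CPM and Ckm from 7.62 ± 4.81 to 575 ± 350.1 CPM. The keratins Krt8 (76.3 ± 31.5 to 0.910 ± 0.139 CPM) and Krt18 (141 ± 22.9 to 2.46 ± 1.08 CPM) and Fgfbp1, a carrier of fibroblast growth factors (26.6 ± 7.08 to 0.0713 ± 0.0868 CPM), fell. Of the interferon list 29 of 32 members rose (31 over the list alone), among them Gbp7 (3.50 ± 0.20). The mature myofibre list had 13 of 16 members higher and 1 lower, the enolase Eno3 (-2.71 ± 0.17, named after its values were seen). The summed level of that list was 1905 ± 109 CPM at day 3 and 1328 ± 345 CPM at day 7, lower although most members rose. Satellite cell identity had 16 of 22 members higher, with Chodl at 4.99 ± 0.31. Members higher were, of secreted growth factors, 21 of 34, with Igf2 rising from 19.8 ± 3.63 to 384 ± 75.2 CPM, and of extracellular matrix 33 of 38. All 50 nuclear oxidative phosphorylation genes fell. So did 76 of 82 ribosomal protein genes, 35 of 40 cell cycle genes, with Rrm2 at -1.74 ± 0.12, and 11 of 16 glycolysis genes. Of the pericyte list 13 of 13 members rose and of the Schwann list 10 of 11. Adjusted over the list alone, the counts were 13 for mature myofibre, 16 for satellite cell identity, 22 for growth factors, 33 for extracellular matrix, 50 for oxidative phosphorylation, 76 for ribosomal proteins, 35 for cell cycle, 11 for glycolysis, 13 for pericyte and 10 for Schwann genes. edgeR called 4926 higher and 4939 lower of 16597 genes. Camera called 16 of 27 lists and fry 18, and with an estimated correlation camera called 0 (lowest adjusted p = 0.226 with an estimated correlation).

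In control FAPs, cell cycle genes fell from day 3 to day 7, and Igf2, Fgf10, Mmp2 and Eln were among the genes that rose. Igf2, a fetal growth factor, rose from 2.90 ± 0.605 to 266 ± 190.0 CPM (log2 change 6.53 ± 0.60, edgeR adjusted p = 6.14e-04) and Fgf10 from 0.702 ± 0.250 to 5.61 ± 0.658 CPM. The matrix genes Mmp2 (456 ± 29.4 to 1729 ± 234 CPM) and elastin, Eln (41.4 ± 5.54 to 168 ± 28.4 CPM), rose. Of secreted growth factors 10 of 36 rose and 0 fell (camera adjusted p = 0.00112, adjusted p = 0.182 with an estimated correlation). Of extracellular matrix genes 11 of 38 rose and 3 fell (p = 0.0290, adjusted p = 0.508 with an estimated correlation). The cytokine gene Il11 (50.2 ± 16.7 to 7.70 ± 3.66 CPM) fell. So did 36 of 40 cell cycle genes, with Gins2 at -1.58 ± 0.16, 59 of 81 ribosomal protein genes and 33 of 50 nuclear oxidative phosphorylation genes. Of the interferon list 21 of 32 members rose (28 over the list alone), among them Irf1 (1.62 ± 0.19). Muscle transcripts were low but rose: 14 of 22 myogenic and 8 of 11 mature myofibre genes, such as Ckm from 0.275 ± 0.120 to 17.4 ± 10.2 CPM and Acta1 from 1.3 ± 0.776 to 61.1 ± 31.5 CPM. Erythroid (5 of 5) and tenocyte markers (7 of 10) rose with them. Adjusted over the list alone, the counts were 10 higher and 0 lower for growth factors, 12 and 4 for extracellular matrix, 37 for cell cycle, 73 for ribosomal proteins, 43 for oxidative phosphorylation, 15 for myogenic, 8 for mature myofibre, 5 for erythroid and 9 for tenocyte genes. edgeR called 1863 higher and 1848 lower of 16144 genes. Leaving out control replicate 2, 3 or 4 of day 3 left 1980, 2159 and 2157 in all. Camera called 21 of 28 lists and fry 19, and with an estimated correlation camera called 0 (lowest adjusted p = 0.0879 with an estimated correlation).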

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

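Of the tests in this part, only that of macrophages among the sorted cells had its prediction written before its result was seen, and all others, and its comparison with the other libraries, were chosen after the results they bear on had been seen. The set of library measures, marker sums and check genes searched for libraries far from the rest of their group was itself narrowed after a first wider search had been seen.

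In FAPs at day 3 the inflammatory list was higher with BAT, while the BAT library of replicate 1 was rich in macrophage transcripts, and macrophages make many of the same cytokines. Macrophages in that library are argued against as the whole cause, because the list's median within a pair was still 0.35 on average (SD 0.0859) in the other 3 mice. Macrophages in the BAT libraries of those 3 mice stay open, since the macrophage list's own median there was 0.23 with an SD of 0.443. The summed level of that list was higher with BAT in each of these 3 mice. A response to surgery and tissue insertion in place of brown fat cannot be told apart from an effect of BAT, as 0 libraries came from muscle with a sham operation or another graft. An effect of BAT on the FAPs themselves was not tested and stays open.

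In satellite cells at day 7 the mature myofibre list was lower with BAT. RNA set free from broken fibres is argued against as the whole source if its share was alike in both gates, which was not measured. Control FAPs from the same muscles held only 10.3% of the CPM lost in satellite cells at the upper quartile of 16 members. The median was 7.14%, with 43.0% for Casq1 and 171% for Ampd1. In those FAPs Myh4 was at 0.904, Ckm at 17.3 and Acta1 at 60.7 CPM. A part shared by both gates stays open, since the list also fell in FAPs (adjusted p = 0.00582, adjusted p = 0.563 with an estimated correlation). Mybpc2 was lower there in 4 of 4 mice (-1.03 ± 0.36, adjusted p = 0.953, and -0.07 ± 0.26 for satellite cells minus FAPs). Myh4 (-0.23 ± 0.75) was higher with BAT in FAPs in 2 of 4 mice and Ckm (-0.44 ± 0.26) in 1 of 4. Satellite cells minus FAPs, these 2 were at -1.14 ± 0.56 and -0.65 ± 0.29 (edgeR adjusted p = 0.744 and 0.730). A loss of all differentiating cells in equal measure stays open. The median of 6 early regulators lay 0.42 above that of the mature list (SD 0.258, above 0 in 4 of 4 mice), and its own mean change was -0.19 ± 0.29 (SD). Control satellite cells of day 3 already held Myod1 at 461 and Myog at 673 CPM. Such regulators are not confined to cells with mature transcripts, so that this gap cannot decide. Fewer myofibre fragments in the gate stay open: the log2 changes of 4 members nearly absent from satellite cells at day 3 spanned 0.77, with SEs of up to 0.123, and this does not settle whether they moved as 1 source, and an effect of BAT on the cells themselves, which was not tested, stays open too.

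Macrophage transcripts stood out in 3 day 3 libraries (4720 CPM in satellite cell control replicate 3, 4790 CPM in satellite cell BAT replicate 4 and 10500 CPM in FAP BAT replicate 1 as sums of the list). An exchange of the BAT satellite cell libraries of replicates 3 and 4 stays open, because correlations of deviations from the group mean with the controls went both ways. Over 242 genes higher in satellite cells the mean r was 1.24 higher as labelled (0.819 and 0.923) than exchanged (-0.416 and -0.314), but over all genes the exchanged pairs correlated better (0.525 and 0.416 against -0.222 and -0.357), also over 12860 genes without those over 0.5 (log2) higher in FAP BAT replicate 1 than in the other FAP BAT libraries (0.313 and 0.297 against 0.0226 and -0.144), and not over 10222 genes without genes called over 1 higher in FAPs as well (-0.0326 and 0.0163 against 0.381 and 0.351). Macrophages among the sorted cells are a candidate source that stays open: the 26 members correlated at 0.98 or more between the 3 libraries, but other day 3 libraries reached 0.996 with each other, and free macrophage RNA would give the same profile (Lyz2 was at 953, 1058 and 2530 CPM, although the gate excluded CD45-positive cells). No biological explanation was tested for this pattern.

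Of 144 tests, each of 1 measure in 1 group of 4 libraries, for a library far from the other 3, 38 flagged one. Dixon's gap test was used (gap over range above 0.829). By chance it flags about 1 in 20 (7.2 in all) where values are normal. Normality was not checked and many tests share libraries, so that 38 against 7.2 is no measure of chance. Beside the macrophage sums above, the 3 macrophage-rich libraries stood apart in the neutrophil sum (107, 34.0 and 103 CPM in the same order). Satellite cell control replicate 3 also did so in the endothelial sum (27.5 CPM), the erythroid sum (246 CPM), Pdgfra (13.9 CPM) and Ly6a (32.5 CPM), and satellite cell BAT replicate 4 in Ly6a (42.8 CPM). FAP BAT replicate 1 of day 3 did so in the erythroid sum (409 CPM), the Schwann sum (17.3 CPM) and Myog (88.4 CPM).

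In the day 7 mouse of replicate 3, Xist stood apart in satellite cell control (355 CPM), satellite cell BAT (301 CPM), FAP control (178 CPM) and FAP BAT (163 CPM). In FAPs of the same mouse the macrophage sum was 1330 CPM in control and 1220 CPM with BAT and Myog 7.39 and 9.81 CPM, and its BAT library stood apart in the pericyte sum (985 CPM) and the tenocyte sum (685 CPM). Its control satellite cell library was low in the tenocyte sum (76.6 CPM), and its BAT satellite cell library stood apart in the number of genes detected (22100).

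Other single libraries stood apart in 1 or more measures. Control satellite cell replicate 2 of day 7 did so in the pericyte sum (2890 CPM), the neutrophil sum (18.4 CPM) and Pdgfra (7.0 CPM), BAT satellite cell replicate 4 of day 7 in the lymphocyte sum (3.74 CPM) and BAT satellite cell replicate 2 of day 3 in the tenocyte sum (643 CPM). Among FAP libraries, control replicate 3 of day 3 had a total of 22.7 M counts and an erythroid sum of 11.5 CPM, and BAT replicate 4 of day 3 a total of 32.5 M. At day 7, the 20 most abundant genes took 26.1% in control replicate 2, the mitochondrially encoded share was 2.23% in BAT replicate 4, the erythroid sum was 28.0 CPM in BAT replicate 2 and Ucp1 was 13.0 CPM in control replicate 4.

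The BAT effect at day 3 differed between satellite cells and FAPs by the test of the difference for Chrnd (log2 -9.26), Alox5 (-5.74), Mgl2 (-8.64) and Nup210 (-7.49). All 4 had their counts in FAPs mainly in BAT replicate 1, with 281, 76, 161 and 65 counts there, and 0 of the 4 genes passed without the mouse of that library. Chrnd, Mgl2 and Nup210 had 0 counts and Alox5 1 count in control FAPs, so that these log2 values depend on the prior count and are no measure of size.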

How the results depend on the processing

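Of the alternatives in this part, the fits without the mice with macrophage-rich libraries, the list tests for differences of BAT effects and the leave-one-out of list tests with an estimated correlation were chosen after the data had been seen. All other alternatives were chosen before.

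Size factors by relative log expression kept each count of called genes within 1.5 times. Without the filter on low counts the number of called genes moved from 3 to 206 for BAT in satellite cells at day 7, from 3 to 63 in FAPs at day 3 and from 0 to 145 in FAPs at day 7. For differences of BAT effects it moved from 0 to 1 (days, satellite cells), 0 to 100 (days, FAPs), 4 to 15 (cell types, day 3) and 0 to 183 (cell types, day 7). DESeq2 gave 39, 40 and 26 genes in these BAT comparisons and 8, 1, 12 and 10 in these differences. limma voom gave 5, 10 and 1 in the BAT comparisons and 0 for cell types at day 3. The joint fit of all 32 libraries gave 0 in satellite cells at day 7 and 9 in FAPs at day 3. The called genes Myh4, Ckm, Mybpc2, Saa3, Cxcl5 and Ereg passed with DESeq2, with limma voom and without the filter. The cause was not tested.

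Leaving out the pairing, so that the mouse was no block, ended every call of BAT in satellite cells at day 7 (0 genes), in FAPs at day 3 (0 genes) and between cell types at day 3 (0 genes), and moved the called lists in satellite cells at day 7 from 14 to 6. Without the block the adjusted p was 1.00 for Myh4, Ckm and Mybpc2 and 0.999 for Saa3, Cxcl5 and Ereg. The block changed no other count of calls by over 1.5 times.

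Leaving out 1 replicate or mouse at a time gave 0 to 14 genes for BAT in satellite cells at day 7, 0 to 27 in FAPs at day 3, 0 to 1 in FAPs at day 7, 0 to 1 between days in FAPs, and 0 to 12 between cell types at day 3. It gave 1980 to 4626 genes between days in control FAPs. Called lists ranged from 5 to 16 in satellite cells at day 3, 10 to 14 at day 7, 9 to 16 in FAPs at day 3 and 9 to 17 at day 7. With an estimated correlation, the mature myofibre list of satellite cells at day 7 had an adjusted p of 0.0395 with all mice and of 0.137 to 0.392 with 3, and the inflammatory list of FAPs at day 3 of 0.0367 and of 0.164 to 0.193. Fewer mice take degrees of freedom from these tests, and the cause was not tested further. Without both pairs that held a macrophage-rich library, 1 gene passed for BAT in satellite cells at day 3, and without both mice concerned 2 passed between cell types at day 3, 0 of them among the 4. The direction of Chrnd between cell types reversed without the mouse of FAP replicate 1 (log2 0.17, adjusted p = 1.00, against 0.00986 without the mouse of FAP replicate 4) and without both of these mice (0.23, adjusted p = 1.00), since its FAP counts were all in that mouse's BAT library.

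Camera with an estimated correlation moved the called lists from 10 to 0 and from 14 to 1 in satellite cells at day 3 and day 7, from 13 to 1 and from 10 to 0 in FAPs, from 17 and 19 to 0 between cell types and from 16 and 21 to 0 between days. With fry the counts for BAT were 0, 1, 1 and 0. Over the named genes and their alternatives, 3818 results kept their direction and side of the threshold, 87 passed only under the alternative, 90 no longer passed and 2 reversed, the 2 of Chrnd. These counts pool all comparisons, also those between cell types and between days, and named genes that did not pass. They do not measure how stable the calls for BAT were. Depth sets a limit for genes near the floor of 0.065 to 0.15 CPM. Calls gained without the filter include genes that the filter keeps, such as Cilp in satellite cells at day 7 (edgeR adjusted p = 7.29e-10).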

Other observations

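The tests in this part are the splits of the libraries, whose expectations were written after the results had been seen, and the sums of marker genes were picked after they had been seen.

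Marker sums of other cell types differed between day 3 and day 7 in both directions in control satellite cells. The summed level of pericyte and smooth muscle genes was 75.9 ± 20.3 CPM at day 3 and 1453 ± 966 CPM at day 7 (SD, n = 4 each), that of Schwann and glial genes 96.9 ± 23.6 and 683 ± 349.9 CPM, that of tenocyte genes 68.9 ± 39.4 and 539.5 ± 309.7 CPM and that of FAP identity genes 343 ± 190.2 and 1846 ± 519.99 CPM. The macrophage sum was lower at day 7 (2038 ± 1793 and 350.4 ± 106 CPM), also without the macrophage-rich control replicate 3 of day 3 (916 to 1279 CPM in the other 3 libraries). Most of the day 3 level of Lyz2 (250 ± 469 CPM) and Ptprc (2.56 ± 4.90 CPM) was in that replicate (953 and 9.91 CPM). At day 7 these genes were at 13.0 ± 21.1 and 0.133 ± 0.172 CPM. The sum of the other day 3 libraries therefore cannot be read as macrophage content. The neutrophil sum was 28.3 ± 52.2 and 11.2 ± 4.81 CPM and the erythroid sum 74.5 ± 115 and 55.8 ± 13.1 CPM. Both directions rested on that replicate: the other 3 libraries of day 3 held 1.68 to 2.47 CPM of neutrophil and 7.95 to 33.7 CPM of erythroid genes, below the 8.01 to 18.4 and 40.2 to 70.7 CPM of day 7. Day cannot be told apart from the deposited table here. In FAPs of day 7 the summed erythroid level was 56.1 ± 28.8 CPM in control and 14.7 ± 8.90 CPM with BAT.

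The libraries of each comparison were split in every other way that keeps the pairs or the groups. For BAT against control there are 8 splits of the pairs, too few for a share under 0.05. The real split and the highest of the others gave 0 and 2 genes in satellite cells at day 3, 3 and 3 at day 7, 3 and 0 in FAPs at day 3, and 0 and 0 at day 7. The 8 splits for differences between cell types gave 4 and 0 at day 3 and 0 and 0 at day 7, and those for satellite cells against FAPs 11702 and 0 at day 3 and 7651 and 0 at day 7. As many genes as in the real split came from 8, 2, 1 and 8 of the splits for BAT, from 1 and 8 for the differences between cell types and from 1 and 1 for the cell types. For the difference of BAT effects between days, 35 of 35 splits gave as many genes as the real 0 in each cell type (highest other 0 in satellite cells and 1 in FAPs). Where the real count is 0, every split gives as many by construction, which says nothing on chance. For day 7 against day 3 in control muscle 1 of 35 splits, the real one, gave as many genes in each cell type (9865 and 3711, highest other 0). That share is under 0.05 and the smallest that 35 splits can give. It does not part day from the deposited table.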
